A study of Danio rerio with 4 samples.

How the data were processed

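Endothelial cells of the caudal hematopoietic tissue of 5 dpf zebrafish larvae were sorted on kdrl-driven GFP and lyve1b-driven DsRed, and libraries of enriched mRNA were made with a NEBNext Ultra kit and read on an Illumina NovaSeq instrument, per the labels' protocols. There were 4 samples, 2 of each group, and the labels give each its group and replicate number. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1, RSEM and DESeq2 and the genome build GRCz11, without saying which step each served. Whether reads were counted by strand is not given in the sources used here. The main table holds estimated counts per gene as deposited by the authors. Its columns are named as FPKM per the file headers, but the values are whole numbers that sum to between 15672159 and 18862102 per library, and 9 to 15 genes per library have a count of 0 here and an FPKM above 0 in the other table, so they were treated as rounded estimated counts and used without further change. The second table holds FPKM values (fragments scaled to transcript length and library total), deposited by the authors, and served only for alternative settings.

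The tables list 28346 genes. Of the 25522 Ensembl identifiers, 23608 had a symbol in the gene name table given with the data. The other 2824 rows carry the MSTRG prefix that StringTie gives to assembled loci, and they took 4.95% to 7.51% of the counts of a library and gave 1634 tested and 77 changed genes. The name table gives many zebrafish genes a human-style name without a paralog letter, so 2 paralogs can share a name, and the text adds the identifier where that matters. Estimated counts of close paralogs, such as the genes for haemoglobins, ferritins, ribosomal proteins and JUNB, can share reads, and their split is uncertain. The RefSeq table given with the data is of another build and was used only to trace renamed symbols, and no coordinates are printed.

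Genes were filtered with filterByExpr (minimum count 10), scaled with TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, legacy method without robust estimation, group as the only factor), with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.699. CPM are TMM-scaled. The standard error of a log2 fold is the fold divided by the square root of its F statistic. Where a group had 0 counts in both libraries, the fold is given against a floor of 3 counts over the group, and where it had 1 to 3 counts as a ratio with an exact 95% binomial interval. No list's median changed when its genes with 0 counts were set at this bound, and medians with a library left out are given with such genes set at it. Sets of genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry (limma 3.58.1 in R 4.3.3). Both camera tests compare a list with the other genes, two-sided, and fry tests a list by itself, for a shift in one direction or (mixed) for changes in either direction. Benjamini-Hochberg adjustment was over the 22 lists. With 2 samples in each group, the smallest two-sided exact permutation p for a single value is 0.33, so shares of counts are given per library without a test.

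The groups, the tests, the 22 gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The lists cover vein and lymphatic, arterial and pan-endothelial genes, niche factors, lysosomal, endocytic, basement membrane, cell cycle, immediate early and heat shock, and interferon and inflammatory genes, and markers of erythroid cells, neutrophils, macrophages, blood progenitors and leukocytes, thrombocytes, lymphocytes, stroma, mural cells, skeletal muscle, epidermis, neural and pigment cells. Of 480 list symbols 453 were matched, and a name shared by more than 3 identifiers was left out. Named genes are kdrl and lyve1b, the 10 highest and 10 lowest log2 folds among changed genes with a mean CPM of at least 10, separate groups and an assigned symbol, up to 4 changed members of each list in order of adjusted p (or the 2 most abundant where none changed), and every changed niche factor. Some genes that meet this rule are not reported here. PROX1, kitlga, HEY1, NRARP, PCNA, the MCM genes, gfi1aa, RUNX1, MYB, ptprc, stab1, MRC1 and TBX20 fall outside the rule and were named after their values were seen.

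The alternatives were DESeq2 1.42.0, DESeq2's size factors in edgeR, library totals without scaling, no filter, at least 50 counts in 2 libraries, the edgeR version 4 method, robust estimation, limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM of at least 1, limma on log2(FPKM + 1) without a filter, limma-voom, a replicate block, leaving out haemoglobin, mitochondrial and ribosomal protein genes, a test against a 1.5-fold change, and leaving out each library. The test of the vein and lymphatic list without lyve1b was added after the data were seen.

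The scripts were tested on simulated counts for the 15953 genes of the comparison of vein with non-vein, drawn from the real means, library sizes and dispersion trend with 200 changed genes in each of 3 simulations. edgeR recovered 2.67% of 2-fold, 27.3% of 4-fold, 44.7% of 8-fold and 53.3% of 16-fold changes, and 4.48% of its calls were false. DESeq2 recovered 4% of 2-fold, 40% of 4-fold, 63.3% of 8-fold and 66.7% of 16-fold changes, and 38.7% of its calls were false. A simulated list with a 4-fold change was called in 10 of 10 simulations by camera with the preset correlation, in 2 by fry and in 0 by camera with an estimated correlation, and 0 of 210 unmoved lists were called by any of these tests. The simulated genes were drawn without correlation between them. In the real lists the estimated correlation ranged from -0.124 (neural) to 0.835 (skeletal muscle). The simulation therefore cannot show how often camera with the preset correlation calls unmoved lists of correlated genes.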

Results

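The transcriptome of endothelial cells sorted from the caudal hematopoietic tissue of zebrafish larvae was measured at 5 days post fertilisation. This tissue is a vascular bed of the larval tail in which blood stem and progenitor cells lodge and multiply. The larvae carried GFP under the promoter of kdrl, a vascular endothelial growth factor receptor gene of endothelial cells, and DsRed under that of lyve1b, a hyaluronan receptor gene of veins and lymphatic vessels. Cells positive for both reporters form the vein group and cells with GFP alone the non-vein group, with 2 libraries in each. The comparison asks how vein endothelium of this niche differs in gene expression from the other GFP-positive cells. The non-vein libraries held 18047152 and 18862102 estimated counts and the vein libraries 15672159 and 16409447, so that a count of 0 in a library allows up to 0.159 to 0.191 CPM (counts scaled to the library total). Across genes, which are not independent replicates, log2 CPM correlated at r = 0.878 between the non-vein libraries, 0.834 between the vein libraries and 0.651 to 0.752 between groups. Ribosomal protein genes took 7.75% and 8.66% of the counts in the non-vein libraries against 3.31% and 3.32% in the vein libraries. Mitochondrial transcripts took 3.31% to 4.18%, and the 9 haemoglobin genes 0.414% and 0.523% in non-vein and 0.556% and 1.03% in vein libraries. The 10 most abundant genes of each library held 10.4% and 10.02% of the counts in non-vein and 18.1% and 17.8% in vein. Nothing in the labels says that replicates came from separate pools of larvae, so the p-values measure only the spread between these samples, which may be technical.

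Of the transcripts behind the reporters, only lyve1b could check the labels, since both groups were sorted as GFP-positive. lyve1b, whose promoter defines the double-positive gate, stood at 53.7 and 217 CPM in the non-vein libraries and at 1953 and 1636 CPM in the vein libraries, a 13.3-fold difference (log2 3.73, SE 0.67, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0281, n = 2 and 2). It restates the sort and is no finding. kdrl, whose reporter both groups carry, rose 3.72-fold in vein, from 2477 ± 677 to 9219 ± 1818 CPM (SD, n = 2; edgeR, adjusted p = 0.0177). The log2 fold of lyve1b was 3.05 without non-vein library 1 and 5.06 without non-vein library 2.

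Of 15953 genes tested, 1826 changed, 656 of them higher and 1170 lower in vein (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among them 648 higher and 1138 lower genes differed at least 2-fold, and 4795 genes had an unadjusted p under 0.05. Of the lower genes, 132 had no count in either vein library, and 8 of the higher genes had none in either non-vein library. The count depended on single libraries: 1084 genes changed without non-vein library 1, with 622 of them lower, and 408 were higher without vein library 1. Of the 22 gene lists, 10 stood apart from the other genes by camera with a preset correlation of 0.01. With an estimated correlation 0 of the 22 did, where 1 had an unadjusted p under 0.05 and the smallest adjusted p was 0.453. Fry, which tests a list by itself and not against other genes, called 0 lists for a shift in one direction (9 with an unadjusted p under 0.05, smallest adjusted p = 0.0758) and 17 for changes in either direction (fry mixed, smallest adjusted p = 0.0198).

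**Figure D1:**
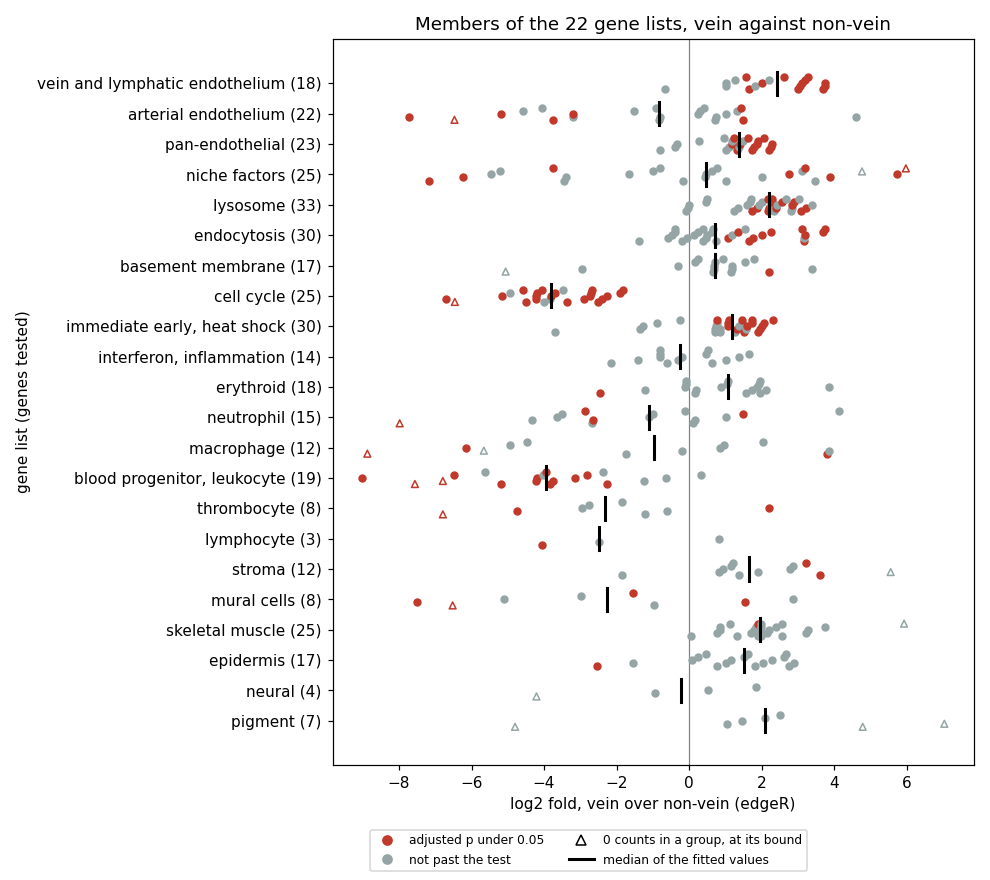
Log2 fold of vein over non-vein (x axis) for each tested member of the 22 gene lists (y axis, genes tested in parentheses), with red symbols for adjusted p under 0.05, grey for the others, triangles for genes with 0 counts in a group drawn at their bound, and a black bar at the median of the fitted values. The cell cycle list has its median at -3.82, and the lysosomal and the vein and lymphatic lists at 2.19 and 2.41.

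Among changed genes with a mean of at least 10 CPM, those with the largest higher fold in vein included enzymes, matrix and niche genes. HMOX1 (ENSDARG00000027529), the inducible heme oxygenase that degrades heme, rose 34.2-fold, from 202 ± 81.2 to 6899 ± 566 CPM (SD, n = 2; edgeR, adjusted p = 0.00985). clec11a, which encodes a secreted lectin described as a growth factor of blood and bone progenitors, rose 16.5-fold (log2 4.05, SE 0.36; edgeR, adjusted p = 0.0120). vcam1b, an adhesion molecule that binds integrins on blood cells, rose 14.6-fold (edgeR, adjusted p = 0.0218). CYP24A1 and cyp1c1, which encode cytochrome P450 enzymes, rose 22.7-fold and 22.6-fold, and the collagen gene col27a1b rose 18.9-fold (edgeR, adjusted p = 0.0190, 0.0177 and 0.0183). SERPINE3 and mapkbp1 rose 335-fold and 36.2-fold, and TBPL2, with 0 counts in the non-vein libraries and 747 in the vein libraries, was at least 306-fold higher. This bound and those below set a group without counts at 3 counts over its 2 libraries and cover counting error only. The log2 fold of CYP24A1, 4.51, was 5.13 without vein library 1 and 3.37 without vein library 2. Without non-vein library 1 that of mapkbp1 was 6.86 in place of 5.18, that of cyp1c1 5.25 in place of 4.50 and that of vcam1b 3.25 in place of 3.87, and without non-vein library 2 that of mapkbp1 was 4.41, that of col27a1b 5.09 in place of 4.24 and that of vcam1b 4.98. SERPINE3 had 3 and 1 counts in the non-vein libraries, and its fold moved by over 1.5 times without either of them.

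By the same rule, the 10 genes with the largest lower fold had no count in the vein libraries. GRAP2, an adaptor of T cell receptor and leukocyte signalling, had 5676 counts over the non-vein libraries and was at least 1540-fold lower in vein (edgeR, adjusted p = 0.00985). cd74b, the invariant chain of antigen presentation, was at least 467-fold lower, with 15.6 and 72.9 CPM in the non-vein libraries. The others were znf296, IRF4, a transcription factor of lymphoid and myeloid cells, rasal3, unc13d, which acts in granule release of leukocytes, PRKCD (ENSDARG00000009208), NEIL3, a DNA glycosylase, FMNL1 and sema7a, with bounds from at least 293-fold for sema7a to at least 367-fold for znf296. PRKCD had 769 and 381 counts in the non-vein libraries. The call of cd74b was lost with limma-voom (adjusted p = 0.116) and that of FMNL1 with limma on log2(FPKM + 1) without a filter (adjusted p = 0.0575).

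**Figure D2:**
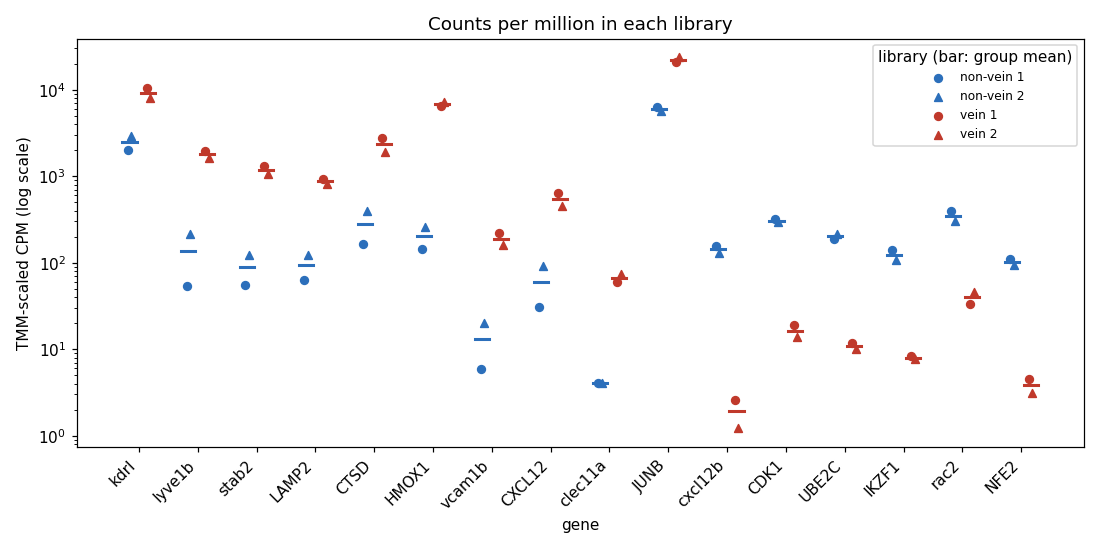
TMM-scaled CPM on a log axis (y) of 16 named genes (x) in each library, with non-vein in blue, vein in red, circles for library 1, triangles for library 2 and bars at the group means. In every gene shown both libraries of a group lie on the same side of the other group, as with CDK1 at 322 and 292 CPM in non-vein against 18.9 and 14.0 CPM in vein.

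Vein and lymphatic endothelial genes rose in vein: 12 of 18 tested members were higher and 0 lower, with 15 higher when adjusted over the list alone, and the median log2 fold was 2.41 (camera, adjusted p = 1.01e-11; adjusted p = 0.453 with an estimated correlation). lyve1b, which defines the gate, is one of them, and without it 11 of 17 were higher and 0 lower, with 14 higher when adjusted over the list alone (median log2 2.2; camera, adjusted p = 9.08e-11; adjusted p = 0.447 with an estimated correlation), a test chosen after the data were seen. stab2, a scavenger receptor for hyaluronan and other waste macromolecules, rose 13.4-fold, from 88.8 ± 47.8 to 1193 ± 168 CPM (SD, n = 2; edgeR, adjusted p = 0.0151). The endocytic adaptor dab2 (ENSDARG00000031761) rose 8.66-fold and its paralog DAB2 (ENSDARG00000053091) 3.15-fold (edgeR, adjusted p = 0.0259 and 0.0212). NR2F1 (ENSDARG00000052695), a nuclear receptor gene of the COUP-TF family, which acts in vein identity, rose 8.05-fold (edgeR, adjusted p = 0.0266). It was matched to nr2f1b by a name that a paralog shares. PROX1, the lymphatic transcription factor, did not pass the test (log2 -0.67, edgeR, adjusted p = 0.81). Within the non-vein group 15 of the 18 members were higher in library 2 than in library 1, by a median log2 of 1.13. Without non-vein library 2 the list median was 3.04, and the log2 folds of stab2, dab2 (ENSDARG00000031761) and NR2F1 were 4.43, 4.13 and 3.86, and without non-vein library 1 that of dab2 (ENSDARG00000031761) was 2.53.

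Lysosomal genes rose in vein, with 13 of 33 tested members higher, 0 lower and 25 higher when adjusted over the list alone (median log2 2.19; camera, adjusted p = 1e-15; adjusted p = 0.453 with an estimated correlation). The membrane protein gene LAMP2 rose 9.35-fold and the protease gene CTSD, for cathepsin D, 8.38-fold (edgeR, adjusted p = 0.0149 and 0.0204). CD63, a tetraspanin of late endosomes, rose 3.33-fold (edgeR, adjusted p = 0.0157). The list took 0.239% and 0.476% of the counts in the non-vein libraries and 1.95% and 1.59% in the vein libraries. Endocytic genes followed, with 11 of 30 higher, 0 lower and 13 higher when adjusted over the list alone (median log2 0.70; camera, adjusted p = 2.37e-07; adjusted p = 0.453 with an estimated correlation). Of these 11, stab1, stab2, MRC1 and both dab2 paralogs also stand in the vein list. The clathrin chain genes CLTA and cltca rose 4.0-fold and 4.74-fold, and RAB5C, a small GTPase of early endosomes, 3.38-fold (edgeR, adjusted p = 0.0151, 0.0191 and 0.0149). Without non-vein library 2 the log2 fold of CTSD was 3.83 in place of 3.07.

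Pan-endothelial genes rose in vein as well: 13 of 23 tested members were higher, 0 lower and 15 higher when adjusted over the list alone (median log2 1.38; camera, adjusted p = 1.33e-09; adjusted p = 0.469 with an estimated correlation). SOX7, a transcription factor of endothelial fate, rose 3.48-fold, EGFL7, a secreted endothelial protein, 3.29-fold, and etsrp, the ETS factor that starts endothelial development, 3.67-fold (edgeR, adjusted p = 0.0157, 0.0157 and 0.0164). These genes took 0.513% and 0.786% of the counts in the non-vein libraries and 2.2% and 1.96% in the vein libraries. Arterial genes moved both ways, with 2 higher and 5 lower of 22, or 3 and 6 when adjusted over the list alone (median log2 -0.83; camera, adjusted p = 0.128). HEY2, a Notch target of arterial endothelium, fell 213-fold in vein, from 35.8 ± 11.1 to 0.16 ± 0.13 CPM (SD, n = 2; edgeR, adjusted p = 0.0144). TBX20, with 0 counts in the vein libraries, was at least 88.7-fold lower, and HEY1 and both CXCR4 genes were the other lower members. The CXCR4 genes, matched by a name without a paralog letter, stand in the blood progenitor and leukocyte list as well. The Notch ligand dll4, an arterial marker, rose 2.79-fold in vein (edgeR, adjusted p = 0.0177), as did an NRARP gene (log2 1.43). Of the basement membrane genes 1 of 17 was higher and 0 lower, over all genes and adjusted over the list alone (median log2 0.70; camera, adjusted p = 0.0781). The list passed in 6 of 16 settings, one of them without non-vein library 2 (median log2 1.29; camera, adjusted p = 0.0491). The higher gene was THBS1 (ENSDARG00000010785), the gene of the matrix glycoprotein thrombospondin 1, which rose 4.56-fold (edgeR, adjusted p = 0.0307). Its call held in 15 of 18 settings, and its adjusted p was 0.0614 without non-vein library 1 and 0.0548 without vein library 2. HEY2 had 1 and 4 counts in the vein libraries.

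Factors of the blood stem cell niche split between the groups, with 5 of 25 tested members higher and 3 lower in vein, or 7 and 4 when adjusted over the list alone (median log2 0.45; camera, adjusted p = 0.421). The paralogs of the chemokine that retains blood stem cells went opposite ways. CXCL12 (ENSDARG00000037116, matched to cxcl12a) rose 9.08-fold, from 60.5 ± 42.6 to 550 ± 131 CPM, and cxcl12b fell 74.7-fold, from 143 ± 19.1 to 1.91 ± 0.990 CPM (SD, n = 2; edgeR, adjusted p = 0.0264 and 0.0104). vcam1b, at 5.98 and 19.97 CPM in non-vein libraries, stood at 218 and 161 CPM in vein libraries. epoa, the erythropoietin gene, rose 52.9-fold in vein, to 19.5 ± 5.70 CPM (SD, n = 2; edgeR, adjusted p = 0.0282). The insulin-like growth factor gene igf2b rose 6.68-fold, and igf2a, with 0 counts in the non-vein libraries, was at least 62.7-fold higher (edgeR, adjusted p = 0.0384 and 0.0463). ANGPT2, a ligand of the TIE2 receptor, fell 13.6-fold, and SELE (ENSDARG00000042138), a gene named for the adhesion molecule E-selectin, had 2 counts in vein against 389 in non-vein, a ratio of 158 with a 95% counting interval of 43.5 to 1310 (edgeR, adjusted p = 0.0293 and 0.0376). The Kit ligand gene kitlga did not pass the test (log2 0.43; edgeR, adjusted p = 0.76). Of 18 settings the call of igf2a held in 9, that of SELE in 12, that of igf2b in 15 and those of CXCL12 (largest adjusted p = 0.0506) and ANGPT2 in 17. That of igf2b was lost without vein library 1 (adjusted p = 0.0568) and that of ANGPT2 without non-vein library 2 (adjusted p = 0.0751). Those of SELE and igf2a were lost without non-vein library 1 (adjusted p = 0.176 and 0.133) and without non-vein library 2 (0.0533 and 0.0967), and that of igf2a without vein library 1 (0.117). Without non-vein library 2 the log2 folds of CXCL12, vcam1b and igf2b were 4.17, 4.98 and 3.82, without non-vein library 1 that of igf2b was 2.13, without vein library 1 that of cxcl12b was -6.88 and without vein library 2 that of ANGPT2 was -4.63, and epoa had 2 and 12 counts in the non-vein libraries.

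Cell cycle genes fell in vein: 21 of 25 tested members were lower, 0 higher and 24 lower when adjusted over the list alone (median log2 -3.82; camera, adjusted p = 1.74e-30; adjusted p = 0.453 with an estimated correlation). CDK1, the kinase of mitotic entry, fell 18.7-fold, from 307 ± 21.1 to 16.4 ± 3.47 CPM (SD, n = 2; edgeR, adjusted p = 0.00985). UBE2C and BIRC5, which act in mitotic exit and chromosome segregation, fell 18.6-fold and 22.8-fold, and the cyclin gene CCNA2 fell 14.1-fold (edgeR, adjusted p = 0.00985 for each). The replication factor gene PCNA and 6 MCM helicase genes were also lower, with log2 folds from -1.84 for MCM4 to -2.90 for PCNA.

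Genes of blood stem and progenitor cells and leukocytes fell in vein, with 13 of 19 tested members lower, 0 higher and 16 lower when adjusted over the list alone (median log2 -3.95; camera, adjusted p = 6.52e-18; adjusted p = 0.453 with an estimated correlation). IKZF1, the lymphoid transcription factor Ikaros, fell 15.4-fold and rac2, a GTPase of leukocyte migration, 8.80-fold (edgeR, adjusted p = 0.0104 and 0.0124). Both genes named CXCR4, for the CXCL12 receptor, fell, ENSDARG00000041959 by 36.3-fold from 1147 ± 326 to 31.6 ± 23.3 CPM and ENSDARG00000057633 by 13.6-fold (SD, n = 2; edgeR, adjusted p = 0.0157 and 0.0120). gata2b, a transcription factor of hemogenic endothelium and blood stem cells, had 3 counts in vein against 2053 in non-vein, a ratio of 557 with a 95% counting interval of 190 to 2700, and gfi1aa was at least 189-fold lower. RUNX1, MYB and ptprc did not pass the test, with log2 folds of -5.63, -2.37 and -4.02. The list took 0.645% and 0.528% of the counts in the non-vein libraries and 0.0746% and 0.107% in the vein libraries. Without vein library 2 the list median was -4.67 and the log2 fold of the CXCR4 gene ENSDARG00000041959 was -6.25, and without vein library 1 the latter was -4.58.

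Markers of mature blood cells were also examined. Thrombocyte genes fell as a list, with 2 of 8 lower and 1 higher, or 4 and 1 when adjusted over the list alone (median log2 -2.31; camera, adjusted p = 0.0172; adjusted p = 0.469 with an estimated correlation). NFE2, a transcription factor of thrombocytes, fell 26.9-fold (edgeR, adjusted p = 0.0104), itga2b, with 0 counts in vein and 317 and 91 in non-vein, was at least 111-fold lower, and THBS1 was the higher member. itga2b stands in the blood progenitor and leukocyte list as well and THBS1 in the basement membrane list. The call of itga2b held in 12 of 18 settings and was lost without non-vein library 1 (adjusted p = 0.216). The list passed in 12 of 16 settings, and its median was -1.66 without vein library 1 and -3.04 without vein library 2. Neutrophil genes had 3 of 15 lower and 1 higher, over all genes and adjusted over the list alone (median log2 -1.10; camera, adjusted p = 0.0511). Among the lower members, LECT2 (ENSDARG00000090889) fell 7.28-fold and cyba 6.34-fold, while srgn, a proteoglycan gene also expressed by endothelium, rose 2.77-fold (edgeR, adjusted p = 0.0144, 0.0274 and 0.0200). The neutrophil list passed in 4 of 16 settings, one of them without vein library 2 (median log2 -2.70; camera, adjusted p = 0.000225), and its median was -0.36 without vein library 1. Without vein library 2 the log2 fold of cyba was -3.46 in place of -2.67. Macrophage genes had 2 of 12 lower and 1 higher, or 5 and 2 when adjusted over the list alone (median log2 -0.98; camera, adjusted p = 0.488). csf1rb, a receptor of macrophage growth factor, fell 70.8-fold and apoeb, the gene of a lipid carrier protein, rose 14.0-fold, to 2560 ± 418 CPM (SD, n = 2; edgeR, adjusted p = 0.0299 and 0.0144). csf1rb had 1 and 28 counts in the vein libraries. With a library left out the macrophage median ranged from -1.85 to -1.21, and without vein library 2 the list had 9 of 17 tested members with 0 counts in a group. Of 3 lymphocyte genes tested 1 was lower and 0 higher, over all genes and adjusted over the list alone (median log2 -2.48; camera, adjusted p = 0.0863). It was CCR9 (ENSDARG00000055186), the receptor of the chemokine CCL25, which fell 16.8-fold (log2 -4.07, edgeR, adjusted p = 0.0164). Its log2 fold was -4.84 without vein library 2. Erythroid genes had 1 of 18 lower and 0 higher, over all genes and adjusted over the list alone (median log2 1.06; camera, adjusted p = 0.116), the lower gene being blf, which fell 5.55-fold (edgeR, adjusted p = 0.0331). The erythroid list passed in 2 of 16 settings, one of them without vein library 1 (median log2 1.59; camera, adjusted p = 0.00694), and its median was 0.13 without vein library 2. The lymphocyte list passed without vein library 2 (camera, adjusted p = 0.0369), and its median ranged from -3.30 to -1.43 with a library left out. The call of blf held in 13 of 18 settings and was lost without non-vein library 1 and without vein library 1 (adjusted p = 0.0594 and 0.0585), and its log2 fold was -3.10 in place of -2.47 without vein library 2.

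Immediate early and heat shock genes, which tissue dissociation can induce, rose in vein, with 15 of 30 tested members higher, 0 lower and 22 higher when adjusted over the list alone (median log2 1.18; camera, adjusted p = 9.09e-11; adjusted p = 0.495 with an estimated correlation). The transcription factor genes JUNB (ENSDARG00000104773) and FOS rose 3.69-fold and 2.76-fold, and ier2a and GADD45B (ENSDARG00000013576) 4.02-fold and 4.96-fold (edgeR, adjusted p = 0.0124, 0.0149, 0.0141 and 0.0144). These transcripts were abundant in both groups: FOS stood at 6386 ± 542 CPM in non-vein and 17647 ± 1091 CPM in vein (SD, n = 2), and the list took 2.68% and 3.04% of the counts in non-vein and 7.25% and 7.92% in vein libraries. Interferon and inflammatory genes had 0 of 14 past edgeR's quasi-likelihood test, and 0 adjusted over the list alone. Their median log2 fold was -0.26 and their mean -0.11, while camera gave the upward direction (adjusted p = 0.976). nfkbiab, an inhibitor of NF-kB, stood at 1326 ± 81.4 CPM in non-vein and 1145 ± 132 CPM in vein, and the chemokine gene cxcl18b at 74.6 ± 96.7 and 102 ± 32.7 CPM (SD, n = 2; edgeR, adjusted p = 0.530 and 0.857). Non-vein library 2 decided the value of cxcl18b, whose log2 fold was 4.03 without it (edgeR, adjusted p = 0.00662).

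Markers of other tissues that a sort can carry over were also examined. Stromal genes rose as a list, with 2 of 12 higher, 0 lower and 4 higher when adjusted over the list alone (median log2 1.64; camera, adjusted p = 0.00478; adjusted p = 0.575 with an estimated correlation). POSTN (ENSDARG00000104267), a matrix protein gene, rose 9.28-fold and MMP2, a matrix protease gene, 12.2-fold (edgeR, adjusted p = 0.0233 and 0.0242). Without vein library 2 the stromal median was 1.24 (camera, adjusted p = 0.0999). Without non-vein library 2 it was 2.28, and the log2 folds of POSTN and MMP2 were 4.18 and 4.63, and without non-vein library 1 that of MMP2 was 3.02. Mural genes had 1 of 8 higher and 3 lower, or 1 and 5 when adjusted over the list alone (median log2 -2.27; camera, adjusted p = 0.116). TAGLN (ENSDARG00000033466), an actin-binding protein gene, rose 2.92-fold, while rgs5b and RGS5, regulators of G protein signalling in pericytes, fell 2.94-fold and 183-fold, and NOTCH3 was at least 91.7-fold lower (edgeR, adjusted p = 0.0157, 0.0198, 0.0311 and 0.0311). The mural list passed in 3 of 16 settings, among them without vein library 1 (camera, adjusted p = 0.0161) and without vein library 2 (camera, adjusted p = 0.0472), and its median was -3.22 without non-vein library 1. The call of rgs5b was lost without vein library 1 (adjusted p = 0.0594) and that of NOTCH3, which held in 12 of 16 settings, without non-vein library 1 or 2 (adjusted p = 0.0517 and 0.118). NOTCH3 had 106 and 232 counts in the non-vein libraries. RGS5 had 0 and 61 counts in the vein libraries, and its call held in 17 of 18 settings (largest adjusted p = 0.0533). Skeletal muscle genes rose as a list, with 1 of 25 higher, 0 lower and 12 higher when adjusted over the list alone (median log2 1.95; camera, adjusted p = 2.37e-07; adjusted p = 0.575 with an estimated correlation). The higher gene was ckma, a muscle creatine kinase (3.69-fold; edgeR, adjusted p = 0.0435), and its call held in 14 of 18 settings and was lost without non-vein library 1 and without vein library 2 (adjusted p = 0.1 and 0.0899). Muscle genes took 0.124% and 0.322% of the counts in the non-vein and 0.446% and 1.16% in the vein libraries, and library 2 was the higher one in both groups, for 23 of 25 members in non-vein (median log2 1.35) and 25 of 25 in vein (median log2 1.48). The muscle median was 2.88 without non-vein library 2 and 1.07 without vein library 2. Epidermal genes had 1 of 17 lower and 0 higher, over all genes and adjusted over the list alone (median log2 1.51; camera, adjusted p = 0.427). It was icn, which fell 5.85-fold (edgeR, adjusted p = 0.0176). The epidermal median was 2.26 without vein library 1 (camera, adjusted p = 0.000676), -1.08 without vein library 2, 0.74 without non-vein library 1 and 2.86 without non-vein library 2. Neural genes had 0 of 4 and pigment genes 0 of 7 past edgeR's quasi-likelihood test (medians -0.22 and 2.08; camera, adjusted p = 0.634 and 0.427), and adjusted over the list alone 0 neural genes, 2 higher and 1 lower pigment genes passed. With a library left out the neural median ranged from -2.53 to 1.13 and the pigment median from -2.82 to 5.33, so that single libraries decided their sign. The myelin gene mbpa and gap43, a gene of growing axons, were at 2.72 ± 0.537 and 1.36 ± 1.07 CPM in non-vein and at 9.73 ± 13.4 and 1.96 ± 2.77 CPM in vein. The pigment enzyme genes named TYRP1 had up to 180 counts in a non-vein and 811 counts in a vein library, and ENSDARG00000029204 had 0 counts in both non-vein libraries and 29 and 291 in the vein libraries (edgeR, adjusted p = 0.0533) and passed in 3 of 17 settings.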

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

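One setting was added after the data were examined, the vein and lymphatic list without lyve1b, and 10 lists then passed as before. All 1826 genes called in the comparison kept the sign of their fold in each alternative that tested them, and no list that passed changed direction. In each called gene both libraries of a group lay above both of the other group. This left little room for a change of sign with the same libraries. The medians of the epidermal, neural and pigment lists and the folds of cxcl18b, mbpa, gap43 and a TYRP1 gene (ENSDARG00000056151), none of which passed in the main fit, changed sign in some settings. The number of calls depended on the method; the cause was not tested except where fewer samples or genes entered. The count of changed genes was 4079 with DESeq2 (1692 higher, 2387 lower), 2845 without a filter (1092 higher), 3213 with the edgeR version 4 method (1332 higher, 1881 lower), 3300 with limma on log2(FPKM + 1) (1163 higher, 2137 lower) and 1055 against a 1.5-fold change (361 higher, 694 lower). Limma on log2(FPKM + 0.1) gave 1769 lower genes, limma on log2(FPKM + 1) without a filter 333 higher genes and limma-voom 1026 higher genes. In simulated counts, 165 of DESeq2's 426 calls over 3 simulations were false (38.7%). That share depends on how many genes truly change, and only a small part of the genes was changed in the simulations. It therefore cannot tell what share of DESeq2's calls in the real data was false. With each library left out in turn, the count ranged from 1084 to 1903, the higher genes from 408 to 942 and the lower genes from 622 to 1313; fewer samples entered those fits, and the lone library of a group was assumed to vary like the others. The log2 fold of kdrl then ranged from 1.64 to 2.2 and that of lyve1b from 3.05 to 5.06, and the number of lists called by camera from 10 to 13. Camera with an estimated correlation and fry's test of a shift in one direction called 0 lists each, and fry's mixed test 17. In simulated data without correlation between genes, camera with an estimated correlation called 0 of 10 moved lists. As to pairing, the labels do not say that equal replicate numbers share a sort, and deviations of same-numbered libraries correlated at 0.0407 across genes. Some lists nevertheless stood higher in library 2 of both groups. In non-vein and vein this held for 23 and 26 of 30 immediate early and heat shock genes and for 14 and 16 of 17 epidermal genes. Other lists did not, such as the lysosomal list with 26 and 10 of 33, so pairing stays undecided. A fit with a replicate block called 1170 genes, 454 higher and 716 lower, and 13 lists. Over all named genes and settings, a call was lost 46 times and gained 4 times. The lists were not tested again with DESeq2, the version 4 method, robust estimation or the 1.5-fold test. At this depth a count of 0 limits a gene to 0.191 CPM or less in each library.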

Other observations

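The list of iron genes, the test of the ribosomal protein genes, those of sequencing depth and abundant genes and those that set the stress, vein marker, lysosomal and endocytic lists against the pan-endothelial list were chosen only after the results were seen, and the second list of blood genes was chosen after the fixed lists were read but before its own values were.

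Of 19 genes of iron and haem handling tested, 8 were higher in vein and 0 lower. The list was drawn up after the values of HMOX1, fthl27, fthl31, blvrb and SLC40A1 had been seen, so the count is no independent evidence of a direction and no test of the list is given. The ferritin-like gene fthl27, for an iron storage protein, was the most abundant of them and rose 9.67-fold, from 3444 and 4414 to 38752 and 37265 CPM (edgeR, adjusted p = 0.00985). Next to HMOX1, the ferritin-like genes fthl31, fthl28 and fthl29, the biliverdin reductase gene blvrb, the haem transporter gene SLC48A1 (ENSDARG00000026109) and SLC40A1, for the iron exporter ferroportin, rose, the last by a log2 of 3.47 (SE 0.61; edgeR, adjusted p = 0.0263). The transferrin receptor gene tfr1b did not pass the test (log2 -1.79; edgeR, adjusted p = 0.128), nor did the other gene named SLC48A1 (ENSDARG00000026907, log2 1.18; edgeR, adjusted p = 0.568). The list took 0.513% and 0.647% of the counts in the non-vein libraries and 4.71% and 4.56% in the vein libraries, and 6 to 9 members were called with a library left out.

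Of 78 ribosomal protein genes, 68 fell in vein and 0 rose, with a median log2 fold of -1.15 (camera, p = 8.78e-24; p = 0.131 with an estimated correlation). The test was chosen after the results were seen, so these p-values are no independent evidence of a direction. RPL3 fell from a mean of 4072 to 1441 CPM (log2 -1.50, SE 0.18; edgeR, adjusted p = 0.0151), and 76 of the 78 had a fold below 0 under TMM, DESeq2's size factors and library totals alone. The number called was 9 without vein library 1 and 27 without vein library 2, with medians of -1.18 and -1.19.

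Blood progenitor, leukocyte and cell cycle genes were lower in vein, with 34 of 44 called and a median log2 fold of -3.84. A vein library total lay at most a log2 difference of -0.267 from a non-vein total. For the share of counts left beside the 17 most abundant genes the largest difference was -0.136. The median had a 95% bootstrap interval over genes of -4.20 to -3.14. Differences this small could not give such a median, and the folds were already scaled for library totals. The comparison could thus hardly have come out otherwise and is no independent evidence on the cause. This interval and the next treat genes as independent and leave out the spread between libraries. A second list of blood genes, none of them in the fixed lists, had a median of -2.96 (95% bootstrap interval over genes -4.69 to -2.11) with 19 of 19 folds below 0, 8 of them called (5 to 13 with a library left out), and of -4.31 with 18 of 19 below 0 without vein library 2, so blood cells among the GFP single-positive cells may account for part of the pattern. Its most abundant genes, PLEK and FERMT3 (ENSDARG00000030938), stood at 108 and 91.6 CPM and at 98.1 and 79.0 CPM in the non-vein libraries and at 7.90 and 17.7 CPM and at 18.0 and 17.2 CPM in the vein libraries; a GFP gate would remove blood cells that carry no GFP. Division of non-vein endothelium and the labelled difference between the groups stay open and untested.

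Immediate early and heat shock genes rose in vein, but their median log2 fold lay 0.203 below that of the pan-endothelial list (difference -0.203, 95% bootstrap interval over genes -0.713 to 0.237). A smaller share of endothelial RNA in the non-vein libraries would lower these genes only if the other cells there expressed them less. Their level in those cells was not measured, so the medians cannot decide whether that share accounts for the rise. An effect of dissociation or sorting that differs between the groups stays open, since tissue without dissociation was not analysed here, as does a difference between vein and non-vein endothelium.

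The same explanation was set against the vein markers and the uptake genes. The median of the vein and lymphatic list without lyve1b lay 0.818 above the pan-endothelial median (95% bootstrap interval over genes 0.0877 to 1.83). That of the lysosomal list lay 0.806 above the same median (0.29 to 1.16). With a smaller share of endothelial RNA alone, a gene's fold would also depend on its level in the other cells of the non-vein libraries. That level was not measured for these lists or the pan-endothelial list, so the differences cannot decide whether the share is the whole cause. These intervals leave out the spread between libraries. The lysosomal median stayed above the pan-endothelial median with each library left out. Without vein library 1, however, these medians were 2.13 and 1.67, closer together than the 2.19 and 1.38 of all libraries. The endocytic genes that are not vein markers lay below the pan-endothelial median (difference -0.876, interval -1.35 to -0.164). Their level in the other cells of the non-vein libraries was not measured, so this difference cannot decide whether the share is enough for them. The interval of the vein list comes close to 0, and the vein identity named by the labels stays open as an untested explanation.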
